A study of Mus musculus with 9 samples.

How the data were processed

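RNA was measured in 9 mouse livers, 4 from GSDMD-NT knock-in mice without Cre and 5 from GSDMD-NT knock-in mice with Alb-cre, all labelled day 42. Groups and replicate numbers came from the sample titles. Per the labels' protocols, libraries were strand-specific, were made after ribosomal RNA depletion and were sequenced as paired ends. Per the submitters' processing notes, fastp 0.23.2 and HISAT2 2.1.0 were used, with genome build GRCm39. The counting tool, its strand setting, the gene annotation release and any gene filter are not given in the sources used here.

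The deposited table held whole-number counts per gene, as the authors made them and with no normalization, for 18954 genes and 9 livers. Genes were identified by versioned Ensembl identifiers paired with symbols in the table. No per-sample column was left unused. In 354 rows all 9 livers had a count of 0, and 33 rows shared their symbol with another row and were kept apart by identifier, the list tests using the row with the higher expression. A mouse annotation of another genome build was used only for transcript lengths and gene types, so no coordinates are given. A length was found for 13836 of the 14004 tested genes.

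Totals were 13361093 to 16823506 counts per liver. The 20 most abundant genes held 21.5 to 30.9% of the counts. Spearman correlations across genes were 0.961 to 0.986 within groups and 0.942 to 0.976 between groups, and genes are not independent replicates. No 2 livers of a group agreed within sampling noise (chi-square per gene at least 15.3). Y-linked genes were counted in each of the 9 livers, so the planned fit with sex as a covariate did not apply.

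Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (14004 genes, leaving out 4950) were scaled by TMM (factors 0.894 to 1.095) and fitted by group with glmQLFit and glmQLFTest, and p was adjusted by Benjamini-Hochberg over all tested genes, with calls at an adjusted p under 0.05. Standard errors were derived from the log2 fold change and the F statistic. The test was tried on simulated counts for the comparison of GSDMD-NT Alb-cre with control, built on the 14004 tested genes with 200 of them changed. It recovered 10.4% of the genes changed 1.5-fold, 61.9% of those changed 2-fold and 90.0% of those changed 4-fold, with 8 false calls, and made 0 calls when no gene was changed. These shares need not hold in the real data, where 18.3% of tested genes were called. Simulated counts were drawn independently, so shifts shared by many genes of a liver were not covered.

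Gene lists for liver cell types, metabolic pathways, stress and immune responses and possible contaminating tissues were fixed before the data were examined, 55 lists with 1325 symbols, of which 1220 were found. Lists with at least 5 tested members (50) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Counts of called members are given over all genes tested and adjusted over the list alone. An exact permutation test of list means over all 126 splits was added after the camera calls were seen.

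The genes named were set by a rule written before the data were examined. It took Gsdmd, Alb, Col1a1, Acta2, Timp1, Fasn, Cyp7a1, Ppara and Afp whatever their result. It took the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 1, non-overlapping groups and an established symbol. For each list described it took the members with the smallest adjusted p, in each direction where both occurred. Not every gene given by this rule is used here. Other genes named were chosen after their values were seen, and these were Hspa5, Col4a1, Col4a2, Col6a3, Clock, Cry1, Dbp and, in the closing section, S100a9, Prtn3, Lcn2, the other clock genes, the genes of the lists made after the data were seen and those of the other lists described there.

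Alternatives fixed in advance were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (CPM of at least 1 in at least 4 livers), replicate blocks on the title number and on the description number, each liver left out, a test against a 1.5-fold change, removal of mitochondrially encoded genes and the 20 most abundant genes, and 1 surrogate variable from sva 3.50.0. A length-corrected fit, with an offset per liver from a smooth curve of expression on transcript length, and a fit without controls 2 and 4 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.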

Results

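The data were gene counts from mouse liver, read by strand-specific RNA sequencing after depletion of ribosomal RNA. All mice carried 1 knock-in allele for GSDMD-NT, the N-terminal part of gasdermin D, a protein that forms pores in membranes once it is cut free. In 5 livers the mice also carried 1 Alb-cre allele, which expresses Cre recombinase from the albumin promoter, active in hepatocytes, and the 4 controls had no Cre. No liver carried Alb-cre without GSDMD-NT. An effect of Cre or of the Alb-cre allele itself therefore cannot be told apart from one of GSDMD-NT. The series describes the cross as a doxycycline-induced model of hepatocyte death and liver fibrosis, and all livers were labelled day 42. Obeticholic acid, which the series also names, is in the labels of none of the samples analysed here. The labels do not state that the livers came from separate animals, nor their litter, sex or collection time. The livers were read as male, since Y-linked genes were counted in each (Eif2s3y at 725 to 924 counts). The p-values measure the spread between these samples, which may in part be technical. Total counts ran from 13361093 to 16823506 per liver, with 17415 to 17775 genes detected. Levels below are TMM-scaled CPM as mean ± SD over 4 controls or 5 GSDMD-NT Alb-cre livers. Log2 fold changes are GSDMD-NT Alb-cre minus control ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

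The first question was which genes differed between livers with and without Alb-cre. Of 14004 genes tested, 1296 were higher and 1270 were lower in the GSDMD-NT Alb-cre livers at an adjusted p under 0.05. Of these, 294 and 367 changed at least 2-fold. Gsdmd itself measured 38.8 ± 7.17 CPM in controls and 41 ± 7.16 CPM in GSDMD-NT Alb-cre livers (log2 fold change 0.08 ± 0.16, adjusted p = 0.765), a difference smaller than the spread between livers. Whether reads of the inserted GSDMD-NT sequence were counted under Gsdmd is not given in the sources used here, so this value does not check the genotypes. Alb, whose promoter drives Cre, measured 54200 ± 6074 CPM in controls and 43040 ± 5751 CPM in GSDMD-NT Alb-cre livers (log2 fold change -0.33 ± 0.20, adjusted p = 0.271). The first principal component held 40.9% of the variance and placed the 4 controls on one side and the 5 GSDMD-NT Alb-cre livers on the other. The counts depended on which livers were included. They were 567 higher and 627 lower without control 2, 588 and 625 without control 4, 755 and 658 without GSDMD-NT Alb-cre 1, and 805 and 801 without GSDMD-NT Alb-cre 5. With controls 2 and 4 both left out, a setting chosen after these counts were seen, 2 controls remained and 29 genes were higher and 44 lower.

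Among called genes whose levels did not overlap between the groups, the largest rises were led by Saa1, an acute phase apolipoprotein made by hepatocytes, at 40.5 ± 23.7 CPM in controls and 5970 ± 7722 CPM in GSDMD-NT Alb-cre livers (log2 fold change 7.20 ± 1.27, adjusted p = 0.00586). The cytochrome P450 genes Cyp2c69 (log2 fold change 3.66 ± 0.34, adjusted p = 3.77e-04) and Cyp2c40 (log2 fold change 3.15 ± 0.20, adjusted p = 1.91e-05) were also higher. Cyp2c40 rose from 5.55 ± 1.73 CPM to 49.1 ± 3.27 CPM. Both belong to a family of near-identical neighbours, and reads shared between its members could have been split by the counting. The other large rises were those of the zinc finger gene Zfp9 (3.49 ± 0.28, adjusted p = 2.16e-04), the metalloreductase gene Steap4 (3.31 ± 0.61, adjusted p = 0.00642), Bhlha15, a transcription factor of secretory cells (2.94 ± 0.60, adjusted p = 0.00939), the secreted hepatocyte protein gene Fgl1 (2.80 ± 0.57, adjusted p = 0.00897) and Zbtb7c (2.80 ± 0.52, adjusted p = 0.00642). The largest fall was that of Clec2h, a C-type lectin gene, from 15.1 ± 8.22 CPM to 0.703 ± 0.679 CPM (log2 fold change -4.38 ± 0.56, adjusted p = 0.00182). Cib3 (-2.81 ± 0.48, adjusted p = 0.00512), the neurotrophin receptor gene Ntrk2 (-2.75 ± 0.46, adjusted p = 0.00484), the acetylcholine receptor gene Chrna4 (-2.63 ± 0.52, adjusted p = 0.00848) and the prostaglandin D synthase gene Ptgds (-2.51 ± 0.44, adjusted p = 0.00559) also fell. So did the immediate early gene Egr1 (-2.64 ± 0.47, adjusted p = 0.00594), the imprinted RNA gene H19 (-2.44 ± 0.41, adjusted p = 0.00484) and the steroid dehydrogenase gene Hsd17b6 (-2.33 ± 0.50, adjusted p = 0.0108). Each of these 16 calls stood in all 9 fits that left out 1 liver. In all, 1980 called genes had non-overlapping groups, and 18.5% of all tested genes did, against 1.59% for a random order of the 9 livers.

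Genes were also read through 55 lists chosen before the data were examined, of which 50 had at least 5 tested members. The members called by edgeR in 23 of these lists are plotted by list. Camera, which compares a list with all other genes at a preset inter-gene correlation of 0.01, called 14 lists, 3 higher and 11 lower. These list calls were weak. With an estimated correlation 0 lists were called (lowest adjusted p = 0.113), and fry, which tests whether a list moves one way on balance, called 7, of which camera had called 6. An exact permutation test of each list's mean over all 126 splits, chosen after the camera calls were seen, called 0 after adjustment, with 10 lists at an unadjusted p under 0.05 and a smallest possible p of 0.00794. Even at this smallest p a list could pass adjustment over 50 lists only if several others reached it too, so the 0 calls say little. Of 100 splits of the livers, the real one included, 77 gave camera at least 14 lists, whereas no other split gave more than 532 higher or 537 lower genes. The lists are therefore described below by their called genes. Of all tested genes 18.3% were called, so a list near or below that share held no more calls than genes at large. Among the 23 lists plotted, the share was lower for stellate cell, remodelling enzyme, bile acid synthesis and ribosomal protein genes. It was also lower for fatty acid synthesis, fatty acid oxidation and immediate early genes.

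**Figure D1:**
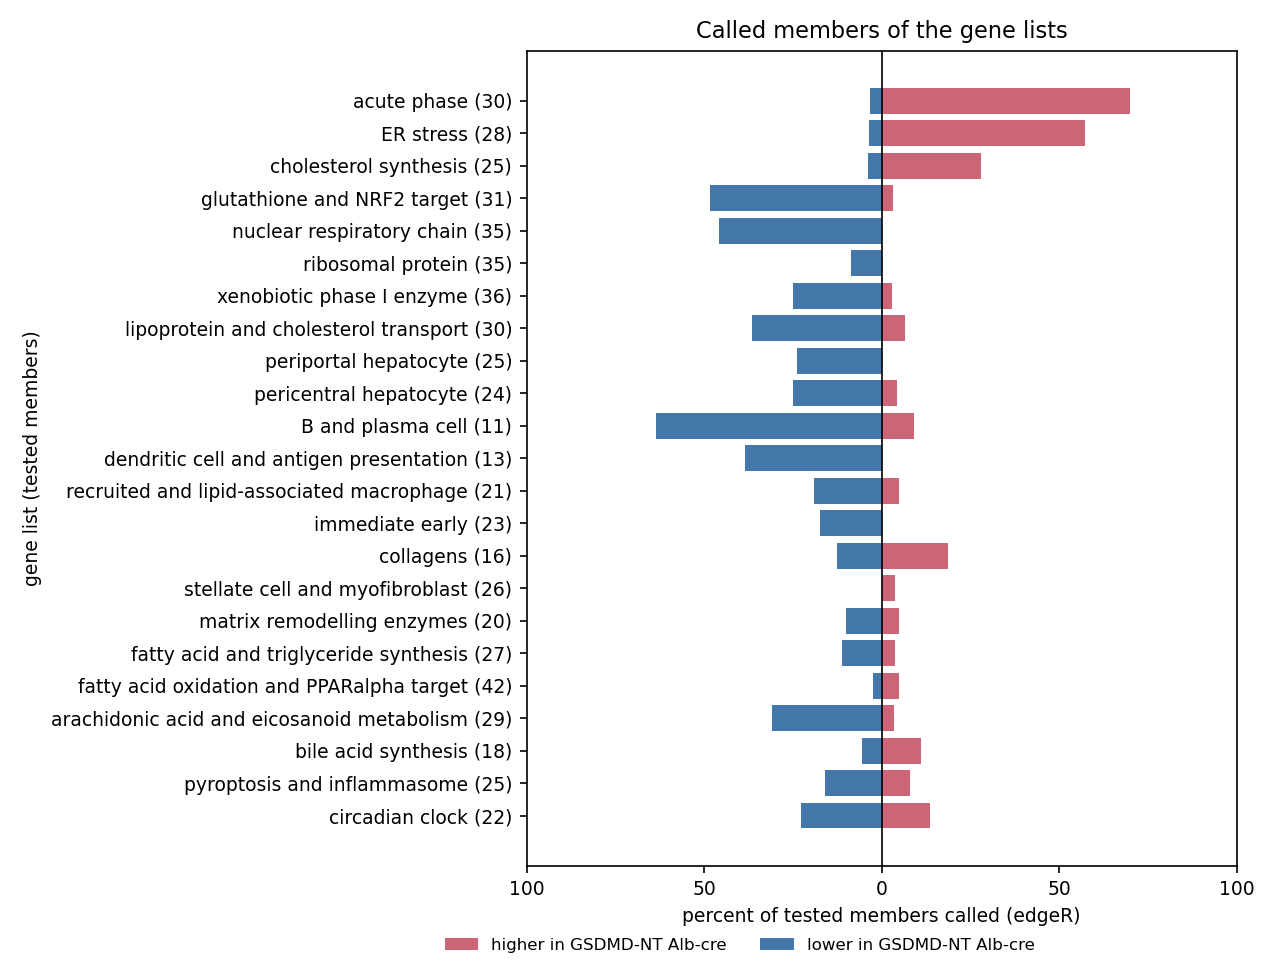
Percent of the tested members of 23 gene lists that were called higher (right, red) or lower (left, blue) in GSDMD-NT Alb-cre livers (n = 5) than in controls (n = 4) by edgeR at an adjusted p under 0.05, with the number of tested members in brackets. The acute phase and ER stress lists held the most higher members, 21 of 30 and 16 of 28, and 15 of 31 glutathione and NRF2 members were lower.

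Acute phase genes, which hepatocytes switch on in response to inflammatory cytokines, were higher in most GSDMD-NT Alb-cre livers. Of 30 tested members 21 were higher and 1 was lower (23 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 1.84 (adjusted p = 6.39e-08 by camera, adjusted p = 0.772 with an estimated correlation). Besides Saa1 and Steap4, the calls with the smallest adjusted p were Stat3, a transcription factor that carries interleukin-6 signals, at 89.1 ± 8.07 CPM in controls and 257 ± 98.1 CPM in GSDMD-NT Alb-cre livers (log2 fold change 1.53 ± 0.26, adjusted p = 0.00492), and the protease inhibitor gene Serpina3m (log2 fold change 1.83 ± 0.32, adjusted p = 0.0057). Serpina3m has close paralogs that could share its reads. Hamp2, a paralog of the iron hormone hepcidin gene, was the 1 lower member (log2 fold change -2.47 ± 0.54, adjusted p = 0.012). The rise was uneven. Averaged over the list, expression stood above the control mean by 3.41 on the log2 scale in GSDMD-NT Alb-cre 2, 2.50 in 5, 1.79 in 1 and 1.32 in 4, but by 0.00 in GSDMD-NT Alb-cre 3, while the controls lay between -0.23 and 0.32. Saa1 reached 19310 CPM in GSDMD-NT Alb-cre 2 and 88.7 CPM in 3, against at most 74.7 CPM in a control. The number of higher members was 10 without control 2, 11 without control 4 and 12 without control 3, and 18 without GSDMD-NT Alb-cre 2.

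**Figure D2:**
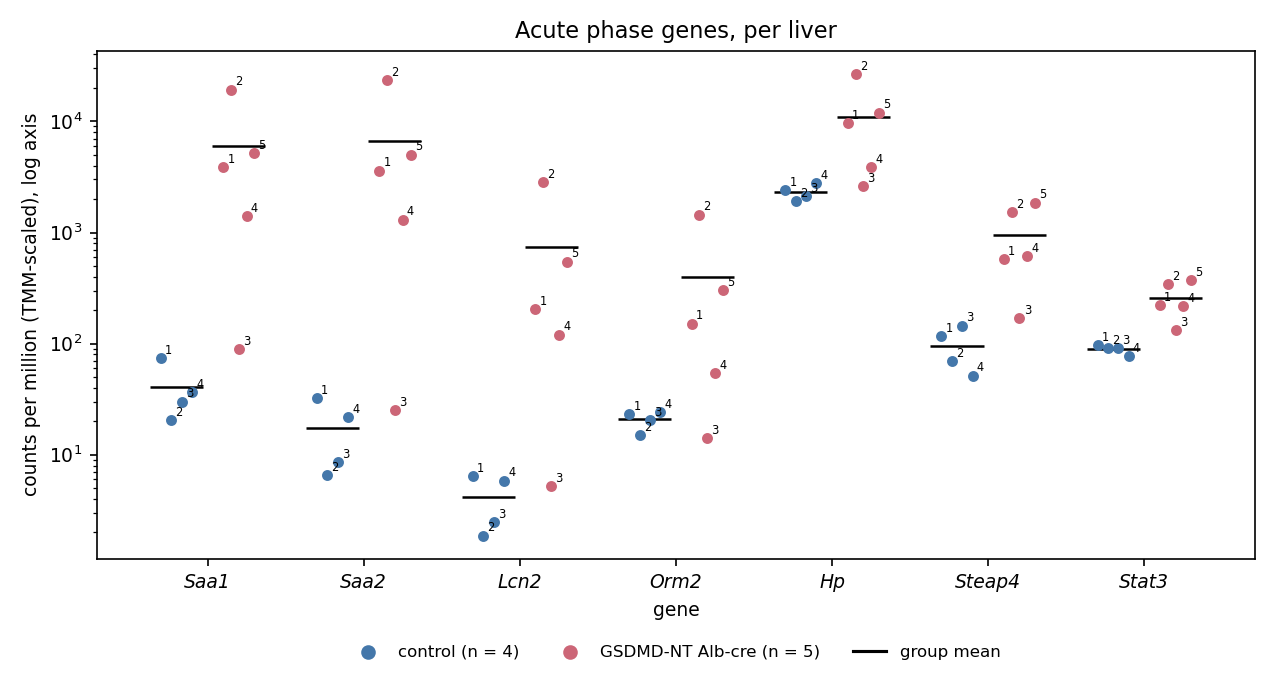
Level of 7 acute phase genes in each liver (points numbered by replicate, log axis in TMM-scaled CPM), with a bar at each group's mean. For Saa1 the controls lay between 20.6 and 74.7 CPM and the GSDMD-NT Alb-cre livers between 88.7 (liver 3) and 19310 CPM (liver 2). In GSDMD-NT Alb-cre liver 3, Saa2, Lcn2 and Hp lay within the controls and Orm2 below them, while Steap4 and Stat3 lay above them.

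Many genes of protein folding in the endoplasmic reticulum were higher as well. In the ER stress list 16 of 28 tested members were higher and 1 was lower (18 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.65 (adjusted p = 2.79e-07 by camera, adjusted p = 0.749 with an estimated correlation). Creld2, a chaperone gene induced by unfolded proteins, rose from 48.9 ± 12.8 CPM to 157 ± 51.8 CPM (log2 fold change 1.68 ± 0.25, adjusted p = 0.00353). The chaperone gene Hspa5 rose from 684 ± 200 CPM to 1249 ± 162 CPM (log2 fold change 0.87 ± 0.20, adjusted p = 0.0142). Trib3, a pseudokinase gene downstream of Atf4 and Ddit3, went the other way, from 17 ± 4.29 CPM to 4.24 ± 1.59 CPM (log2 fold change -1.99 ± 0.27, adjusted p = 0.0025). Hspa5 was singled out after its value was seen. The number of higher members was 9 without control 4 and 10 without control 2.

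The series is about fibrosis, and the genes most used to follow it did not pass the test. Changes may have been missed, since in simulated counts the test recovered 10.4% of genes changed 1.5-fold and 61.9% of those changed 2-fold. These are RNA levels, and deposited matrix was not measured. Col1a1, the main fibrillar collagen gene, measured 20.6 ± 10.2 CPM in controls and 16.7 ± 9.36 CPM in GSDMD-NT Alb-cre livers (log2 fold change -0.30 ± 0.41, adjusted p = 0.633). Acta2, a marker of myofibroblasts, measured 2.94 ± 1.68 CPM in controls and 7.42 ± 9.68 CPM in GSDMD-NT Alb-cre livers (log2 fold change 1.35 ± 0.84, adjusted p = 0.275), with single livers between 0.664 and 23.7 CPM in the GSDMD-NT Alb-cre group. Timp1, an inhibitor of matrix proteases, was below the count filter, with 1 to 5 counts per control and 0 to 11 per GSDMD-NT Alb-cre liver, and was not tested. Among 16 tested collagen genes 3 were higher and 2 lower (3 higher and 2 lower adjusted over the list alone). Col15a1, a basement membrane collagen gene, rose from 8.99 ± 1.48 CPM to 26.1 ± 8.95 CPM (log2 fold change 1.53 ± 0.25, adjusted p = 0.00456). The other higher genes were Col4a1 and Col4a2, also of the basement membrane. Col5a3 fell from 131 ± 51.4 CPM to 41.7 ± 13.9 CPM (log2 fold change -1.65 ± 0.27, adjusted p = 0.00457). Col6a3 was the other lower gene. Of 26 stellate cell and myofibroblast genes 1 was higher and 0 were lower (0 higher and 0 lower adjusted over the list alone). The gene was Gas6 (log2 fold change 1.60 ± 0.52, adjusted p = 0.049). Islr had a log2 fold change of -1.03 ± 0.36, adjusted p = 0.0657. The Gas6 call was lost without control 1, 2, 3 or 4 or GSDMD-NT Alb-cre 1, 2, 4 or 5 (adjusted p = 0.0536 to 0.11). It was also lost in the length-corrected fit, where the stellate cell list had 0 higher and 0 lower members. The stellate cell list's median log2 fold change was -0.24 and its mean 0.00, and camera pointed down. In the matrix remodelling enzyme list 1 of 20 tested members was higher and 2 were lower (1 higher and 2 lower adjusted over the list alone). The gelatinase gene Mmp2 fell from 3.24 ± 0.605 CPM to 1.31 ± 0.553 CPM (-1.29 ± 0.33, adjusted p = 0.0224). Mmp12 was lower (-2.19 ± 0.60, adjusted p = 0.0289) and Mmp19 was higher (0.58 ± 0.18, adjusted p = 0.0437). The Mmp2 call was lost without control 2 or 4 or GSDMD-NT Alb-cre 1 (adjusted p = 0.0528 to 0.0693). That of Mmp12 was lost without control 4 or GSDMD-NT Alb-cre 4 or 5 (adjusted p = 0.0546 to 0.127), and Mmp12 was below the count filter without GSDMD-NT Alb-cre 1. The Mmp19 call was lost without control 2, 3 or 4 or GSDMD-NT Alb-cre 1, 3, 4 or 5 (adjusted p = 0.0531 to 0.11). It was also lost in the length-corrected fit, where the remodelling enzymes had 0 higher and 2 lower members. Collagens as a list gave adjusted p = 0.697 by camera, adjusted p = 0.926 with an estimated correlation. The stellate cell list gave adjusted p = 0.455 by camera, adjusted p = 0.926 with an estimated correlation, and the remodelling enzymes gave adjusted p = 0.436 by camera, adjusted p = 0.898 with an estimated correlation. Higher collagens numbered 2 without control 1, 3 or 4 and in the length-corrected fit. Lower collagens numbered 1 without control 2, 3 or 4 or GSDMD-NT Alb-cre 1, 3 or 5. Higher stellate cell genes numbered 2 without GSDMD-NT Alb-cre 3 and 0 without any other liver, and 1 was lower without control 1 or GSDMD-NT Alb-cre 2 or 4. Higher remodelling enzymes numbered 0 without control 2, 3 or 4 or GSDMD-NT Alb-cre 1, 3, 4 or 5 and 2 without GSDMD-NT Alb-cre 2. Lower remodelling enzymes numbered 0 without control 4 or GSDMD-NT Alb-cre 1 and 1 without control 2 or GSDMD-NT Alb-cre 5. Afp, a fetal liver gene that rises in regenerating and tumour tissue, measured 3.17 ± 1.01 CPM in controls and 2.4 ± 0.698 CPM in GSDMD-NT Alb-cre livers (log2 fold change -0.40 ± 0.29, adjusted p = 0.357).

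**Figure D3:**
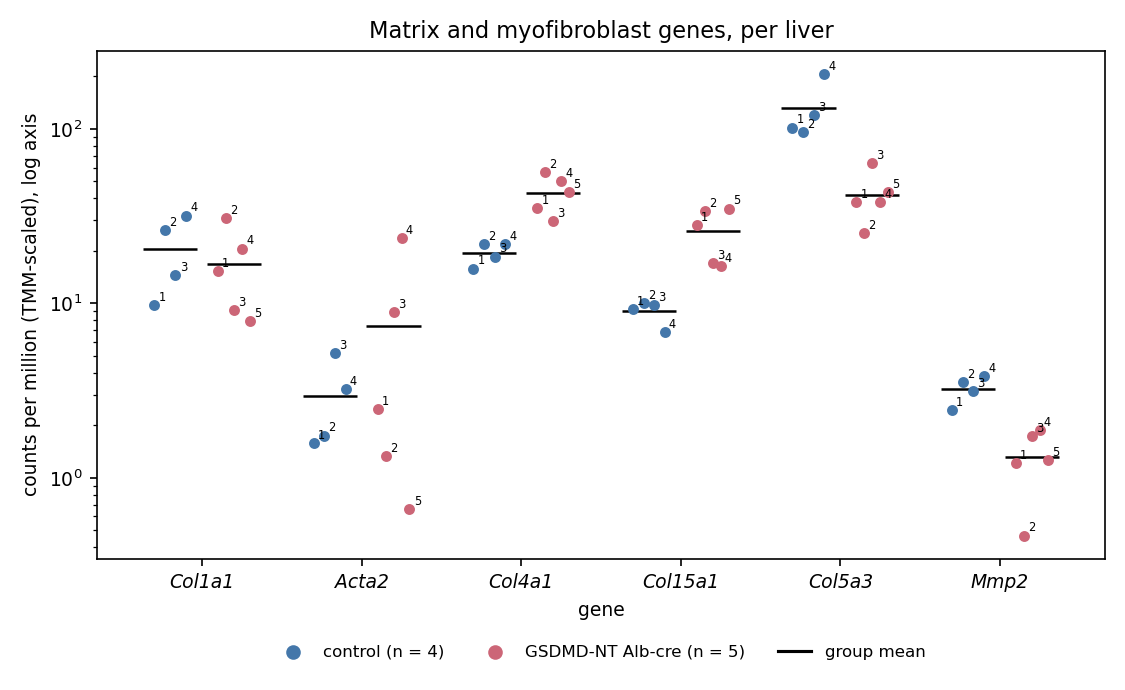
Level of 6 matrix and myofibroblast genes in each liver (points numbered by replicate, log axis in TMM-scaled CPM), with a bar at each group's mean. The groups overlap for Col1a1 and Acta2, Col4a1 and Col15a1 lie higher and Col5a3 and Mmp2 lower in all 5 GSDMD-NT Alb-cre livers.

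The title of the series names lipid metabolism, and its genes moved in different directions. In cholesterol synthesis 7 of 25 tested members were higher and 1 was lower (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0271 by camera, adjusted p = 0.772 with an estimated correlation). Sc5d, a sterol desaturase gene, was the lower member and fell from 542 ± 45 CPM to 379 ± 35.9 CPM (-0.52 ± 0.12, adjusted p = 0.0164). Averaged over the list, the rise was in GSDMD-NT Alb-cre 1, 2 and 5 (0.65, 1.09 and 0.41 above the control mean) and not in 3 and 4 (-0.14 and -0.08), against -0.11 to 0.11 in controls. The number of higher members was 0 without control 2 or 4, 2 without GSDMD-NT Alb-cre 1 or 5, 3 without control 1 and 4 without control 3. The Sc5d call was lost without control 2 (adjusted p = 0.0609), and the number of lower members was 0 without control 2 and 2 without GSDMD-NT Alb-cre 2. The camera call of this list was lost without control 1 or GSDMD-NT Alb-cre 1 or 2 (adjusted p = 0.0622 to 0.246). Of 30 lipoprotein and cholesterol transport genes 11 were lower and 2 higher (3 higher and 11 lower adjusted over the list alone, adjusted p = 0.00501 by camera, adjusted p = 0.749 with an estimated correlation). Soat2, which esterifies cholesterol, fell from 88.3 ± 6.76 CPM to 38.1 ± 7.56 CPM (-1.21 ± 0.14, adjusted p = 0.00104). Abcg5, a subunit of the sterol exporter into bile, fell as well (-1.28 ± 0.23, adjusted p = 0.00617). The cholesterol efflux gene Abca1 rose (0.67 ± 0.15, adjusted p = 0.0134). The number of lower members was 6 without control 2 or 4 or GSDMD-NT Alb-cre 1, and that of higher members was 1 without control 2, 3 or 4 or GSDMD-NT Alb-cre 1 or 5.

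In fatty acid and triglyceride synthesis 1 of 27 tested members was higher and 3 were lower (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.694 by camera, adjusted p = 0.926 with an estimated correlation). The median log2 fold change was -0.07, the mean was 0.005 and camera pointed down. Fasn, the fatty acid synthase gene, measured 1044 ± 382 CPM in controls and 938 ± 332 CPM in GSDMD-NT Alb-cre livers (log2 fold change -0.15 ± 0.28, adjusted p = 0.729). Acacb, whose product makes the malonyl-CoA that holds back mitochondrial fatty acid import, rose (0.93 ± 0.17, adjusted p = 0.00642) and the elongase gene Elovl5 fell (-0.54 ± 0.12, adjusted p = 0.0146). The Elovl5 call was lost without control 2 (adjusted p = 0.0546). Higher synthesis genes numbered 2 without GSDMD-NT Alb-cre 2. Lower synthesis genes numbered 0 without control 2. Fatty acid oxidation and PPARalpha target genes gave 2 higher and 1 lower of 42 (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.342 by camera, adjusted p = 0.926 with an estimated correlation, adjusted p = 0.0196 by camera without GSDMD-NT Alb-cre 3). The nuclear receptor gene Ppara rose from 66.8 ± 15.9 CPM to 115 ± 34.5 CPM (0.78 ± 0.24, adjusted p = 0.0398). Cpt1a, the gate of mitochondrial fatty acid import, was higher (0.64 ± 0.19, adjusted p = 0.0391). The fatty acid binding protein gene Fabp1 was lower (-0.98 ± 0.28, adjusted p = 0.0303). These 3 calls were fragile, and all 3 were lost in the length-corrected fit, where the list had 0 higher and 0 lower members. That of Ppara was lost without control 2 or 4 or GSDMD-NT Alb-cre 1, 3, 4 or 5 (adjusted p = 0.0517 to 0.118), that of Cpt1a without control 2, 3 or 4 or GSDMD-NT Alb-cre 1 or 5 (adjusted p = 0.0548 to 0.0986), and that of Fabp1 without control 2 or 4 or GSDMD-NT Alb-cre 1 or 5 (adjusted p = 0.0615 to 0.0937). Higher oxidation genes numbered 0 without control 2 or 4 or GSDMD-NT Alb-cre 1 or 5 and 1 without control 3 or GSDMD-NT Alb-cre 3. Lower oxidation genes numbered 0 without control 2 or 4 or GSDMD-NT Alb-cre 1 or 5, 2 without GSDMD-NT Alb-cre 2, 3 without control 1 and 6 without GSDMD-NT Alb-cre 3. Among arachidonic acid and eicosanoid genes 9 of 29 were lower and 1, Cyp2c40, was higher (1 higher and 9 lower adjusted over the list alone, adjusted p = 0.218 by camera, adjusted p = 0.772 with an estimated correlation). The phospholipase gene Pla2g12a had the smallest adjusted p of the lower ones (-0.80 ± 0.14, adjusted p = 0.00549). The number of lower members was 3 without GSDMD-NT Alb-cre 1 and 4 without control 2 or 4, and that of higher members was 2 without GSDMD-NT Alb-cre 2. In bile acid synthesis 2 of 18 members were higher and 1 was lower (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.869 by camera, adjusted p = 0.978 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of the classical pathway, rose from 49.2 ± 26.9 CPM to 176 ± 103 CPM (1.84 ± 0.43, adjusted p = 0.0158). Its call was lost without control 2 or 4 (adjusted p = 0.0529 to 0.0579). Akr1c6 fell (-0.94 ± 0.21, adjusted p = 0.0122). Higher bile acid genes numbered 0 without control 2 or 4 and 1 without control 3 or GSDMD-NT Alb-cre 1, 2, 4 or 5. Lower bile acid genes numbered 2 without GSDMD-NT Alb-cre 3.

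Some detoxification genes were lower. Of 31 glutathione and NRF2 target genes 15 were lower and 1 was higher (3 higher and 17 lower adjusted over the list alone). The median log2 fold change was -0.44 (adjusted p = 5.89e-07 by camera, adjusted p = 0.126 with an estimated correlation). The glutathione transferase genes Gstm3 (from 119 ± 35.1 CPM to 26.8 ± 6.4 CPM, -2.15 ± 0.22, adjusted p = 7.55e-04) and Gstm1 (from 1951 ± 402 CPM to 702 ± 63.2 CPM, -1.48 ± 0.16, adjusted p = 9.51e-04) had the smallest adjusted p among the lower members. Both have close paralogs that could share reads. The higher member was the metallothionein gene Mt1 (log2 fold change 5.71 ± 1.13, adjusted p = 0.00827), which is also in the acute phase list. The number of lower members stayed between 12 and 15 with any 1 liver left out, and that of higher members was 3 without GSDMD-NT Alb-cre 3. Of 36 phase I enzymes 9 were lower and 1 was higher (2 higher and 12 lower adjusted over the list alone, adjusted p = 0.00286 by camera, adjusted p = 0.772 with an estimated correlation). Adh1, an alcohol dehydrogenase gene, fell from 1930 ± 250 CPM to 1202 ± 154 CPM (-0.68 ± 0.15, adjusted p = 0.0126). Cyp3a13 rose (0.87 ± 0.18, adjusted p = 0.00969). The list mean lay at -1.10 in GSDMD-NT Alb-cre 2, at -0.42 to -0.17 in 1, 4 and 5, and at 0.05 in 3, inside the control range of -0.15 to 0.10. The count of lower members was 2 without control 2 or GSDMD-NT Alb-cre 1 and 4 without control 4, and that of higher members was 2 without control 2 or GSDMD-NT Alb-cre 2.

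Some markers of both ends of the liver lobule were lower. In the periportal list 6 of 25 members were lower and 0 higher (1 higher and 10 lower adjusted over the list alone, adjusted p = 0.0245 by camera, adjusted p = 0.767 with an estimated correlation). Among them were Hsd17b6 and the histidine ammonia-lyase gene Hal (-0.92 ± 0.23, adjusted p = 0.0213). The Hal call was lost without control 1 or 4 or GSDMD-NT Alb-cre 1 (adjusted p = 0.0536 to 0.0583). The count was 1 without control 4 or GSDMD-NT Alb-cre 1, 2 without control 1 or GSDMD-NT Alb-cre 5 and 3 without control 2. Without control 1 or GSDMD-NT Alb-cre 3 or 4 it had 1 higher member, and the camera call was lost without control 1 (adjusted p = 0.0626). In the pericentral list 6 of 24 were lower and 1 was higher (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.0269 by camera, adjusted p = 0.772 with an estimated correlation). Averaged over the list, GSDMD-NT Alb-cre 3 (-0.13) and 4 (-0.15) lay within the controls (-0.17 to 0.16), as 3 did for the periportal list (-0.11 against -0.13 to 0.07). Lect2, a secreted target of beta-catenin, fell (-0.77 ± 0.13, adjusted p = 0.0057) and the aryl hydrocarbon receptor gene Ahr rose (1.08 ± 0.19, adjusted p = 0.00586). Those lower numbered 2 without control 2 or GSDMD-NT Alb-cre 1 and 3 without GSDMD-NT Alb-cre 5. Higher pericentral genes numbered 2 without GSDMD-NT Alb-cre 3, and the camera call was lost without control 2 or 3 (adjusted p = 0.0575 to 0.0714).

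Of 35 nuclear genes of the respiratory chain 16 were lower in the GSDMD-NT Alb-cre livers, 0 were higher and 19 were not called (0 higher and 23 lower adjusted over the list alone). The median log2 fold change was -0.36 (adjusted p = 2.94e-06 by camera, adjusted p = 0.767 with an estimated correlation). The complex I gene Ndufa1 fell from 77.5 ± 11.4 CPM to 48.8 ± 0.922 CPM (-0.67 ± 0.11, adjusted p = 0.00492). The complex IV gene Cox6c fell from 187 ± 32.9 CPM to 120 ± 9.88 CPM (-0.64 ± 0.13, adjusted p = 0.00939). The count was 5 without control 2, 6 without control 4 or GSDMD-NT Alb-cre 1 and 7 without GSDMD-NT Alb-cre 5. Ribosomal protein genes gave 3 lower and 0 higher of 35 (0 higher and 2 lower adjusted over the list alone), with Rpl19 (-0.62 ± 0.14, adjusted p = 0.0146) and Rpl30 (-0.51 ± 0.13, adjusted p = 0.0227) having the smallest adjusted p. The median was -0.24 (adjusted p = 0.00252 by camera, adjusted p = 0.772 with an estimated correlation). Averaged over the list, GSDMD-NT Alb-cre 2 (0.07) lay within the controls (-0.10 to 0.11). The Rpl30 call was lost without control 2 or 4 or GSDMD-NT Alb-cre 1 or 5 (adjusted p = 0.0524 to 0.0657), and the list's count was 1 without control 2 or 4 or GSDMD-NT Alb-cre 1 or 5 and 10 without GSDMD-NT Alb-cre 2. Both lists hold short transcripts, and the relation of expression to transcript length differed between the groups on average. Of 10 equal groups of genes ordered by length, the shortest had a median log2 fold change of -0.22 and the longest 0.11. The slope of expression on length averaged -0.05 log2 units per doubling in controls and 0.04 in GSDMD-NT Alb-cre livers (exact permutation test, two-sided, p = 0.0238). Controls 2 and 4 lay at its lower end. The groups overlapped, with a slope of 0.0019 in control 3 and -9e-04 in GSDMD-NT Alb-cre 2. Control 4 also had the highest share of mitochondrially encoded counts, 9.55% against 4.23 to 6.88% in the other livers. In a fit corrected for length, chosen after this trend was seen, the respiratory chain list had 4 lower members and a median of -0.24, and the ribosomal list had 2 and -0.09. Camera gave adjusted p = 0.00751 and 0.337.

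**Figure D4:**
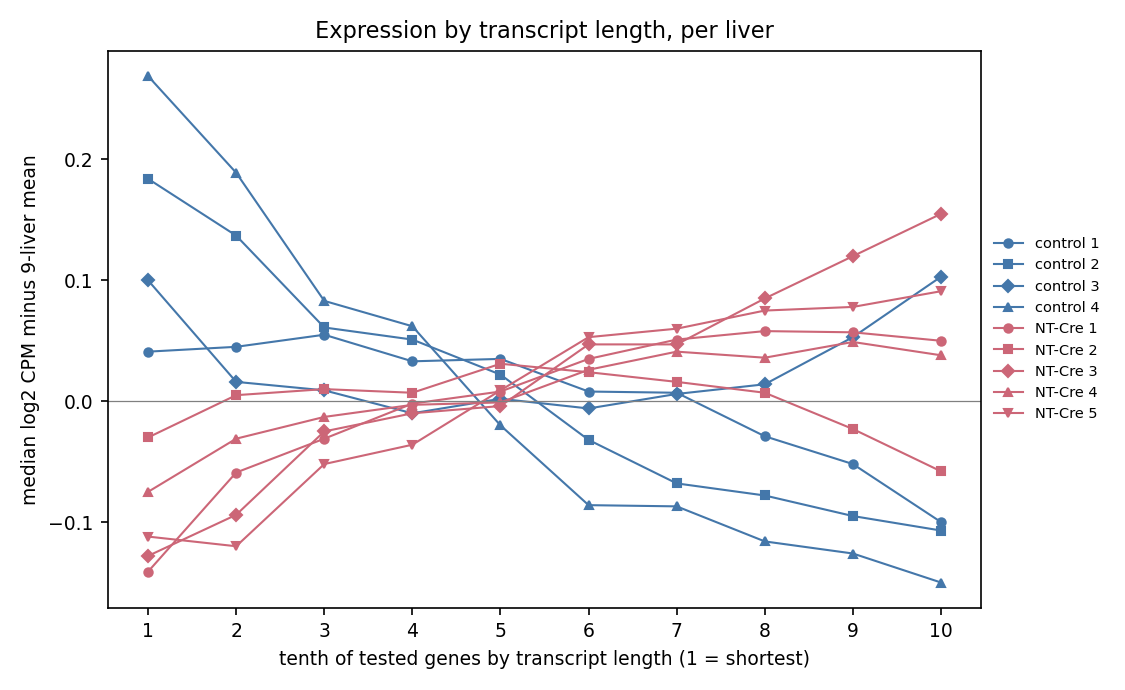
Median log2 CPM minus the 9-liver mean (vertical axis) for 10 equal groups of tested genes ordered by transcript length (horizontal axis, 1 = shortest), with 1 line per liver, controls in blue and GSDMD-NT Alb-cre livers in red. The shortest group lay at 0.27 in control 4 and 0.18 in control 2, and at -0.14 in GSDMD-NT Alb-cre 1. Against the trend of the groups, the longest lay at 0.10 in control 3 and -0.06 in GSDMD-NT Alb-cre 2.

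Some markers of B cells, antigen-presenting cells and recruited or lipid-associated macrophages were lower. Of 16 tested resident Kupffer cell genes 2 were higher and 0 lower. B and plasma cell genes gave 7 lower and 1 higher of 11 (1 higher and 7 lower adjusted over the list alone). The median log2 fold change was -1.34 (adjusted p = 8.22e-05 by camera, adjusted p = 0.113 with an estimated correlation). The B cell receptor genes Ighd (1.93 ± 0.186 CPM in controls and 0.448 ± 0.213 CPM in GSDMD-NT Alb-cre livers, -2.09 ± 0.35, adjusted p = 0.00492) and Cd79a (-2.31 ± 0.42, adjusted p = 0.00617) fell, at levels near 2 CPM in controls. The plasma cell gene Mzb1 was higher (1.74 ± 0.55, adjusted p = 0.0454), but it was tested in only 5 of the 9 fits that left out 1 liver. The Mzb1 call was lost without control 1, 3 or 4 (adjusted p = 0.0925 to 0.0977), and Mzb1 was below the count filter without GSDMD-NT Alb-cre 1, 2, 3 or 4. Higher genes of this list numbered 0 without control 1, 3 or 4 or GSDMD-NT Alb-cre 1, 2, 3 or 4. The number of lower B cell genes was 3 without control 4 and 4 without control 1 or GSDMD-NT Alb-cre 1. Of 13 antigen presentation genes 5 were lower and 0 higher (0 higher and 6 lower adjusted over the list alone, adjusted p = 7.73e-04 by camera, adjusted p = 0.767 with an estimated correlation). The smallest adjusted p were those of the class II genes H2-Aa (from 43.6 ± 17 CPM to 17.8 ± 5.04 CPM, -1.29 ± 0.26, adjusted p = 0.00848) and H2-Eb1 (-1.26 ± 0.26, adjusted p = 0.00987), and 3 were lower without control 4. Averaged over the list, GSDMD-NT Alb-cre 2 (-0.30) lay within the controls (-0.33 to 0.52), as it did for the macrophage list (-0.03 against -0.43 to 0.57). Recruited and lipid-associated macrophage genes gave 4 lower and 1 higher of 21 (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.00501 by camera, adjusted p = 0.772 with an estimated correlation). Lpl, a lipoprotein lipase that other liver cells also express, fell (-1.69 ± 0.26, adjusted p = 0.00386), as did Gpnmb (-2.82 ± 0.55, adjusted p = 0.00795). The endotoxin co-receptor gene Cd14, which hepatocytes can express too, rose (2.75 ± 0.71, adjusted p = 0.0228). The Cd14 call was lost without control 1, 2 or 4 (adjusted p = 0.0506 to 0.0667). Lower macrophage genes numbered 2 without control 4 or GSDMD-NT Alb-cre 1, 4 or 5 and 9 without GSDMD-NT Alb-cre 2, and higher ones 0 without control 1, 2 or 4. Among 25 pyroptosis and inflammasome genes 2 were higher and 4 lower (3 higher and 4 lower adjusted over the list alone, adjusted p = 0.455 by camera, adjusted p = 0.772 with an estimated correlation). The cytokine gene Il18 fell (-0.76 ± 0.16, adjusted p = 0.0099), as did the gasdermin gene Gsdme (-0.58 ± 0.15, adjusted p = 0.0213). The guanylate-binding protein gene Gbp2 rose (1.00 ± 0.26, adjusted p = 0.0226). The Gsdme call was lost without control 2 or 4 (adjusted p = 0.0549 to 0.0658), and that of Gbp2 without control 2 or GSDMD-NT Alb-cre 1 (adjusted p = 0.0591 to 0.0672). Higher pyroptosis genes numbered 0 without control 2 and 1 without control 1, 3 or 4 or GSDMD-NT Alb-cre 1, 2, 4 or 5. Lower pyroptosis genes numbered 1 without control 2 or 4 and 2 without GSDMD-NT Alb-cre 1.

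Clock genes changed in both directions. Of 22 tested members 5 were lower and 3 higher (4 higher and 7 lower adjusted over the list alone, adjusted p = 0.138 by camera, adjusted p = 0.772 with an estimated correlation). The repressor gene Nr1d1 fell from 152 ± 50.8 CPM to 41 ± 7.32 CPM (-1.89 ± 0.20, adjusted p = 9.51e-04) and Per3 from 60.7 ± 7.5 CPM to 31.2 ± 3.62 CPM (-0.96 ± 0.12, adjusted p = 0.00179). The higher members were Clock, Cry1 and Fkbp5 (1.62 ± 0.26, adjusted p = 0.00438), a chaperone gene that also responds to glucocorticoids. The number of higher members was 1 without control 4, and camera called the list without control 4 (adjusted p = 0.0346). Camera also called it in the length-corrected fit (adjusted p = 0.0476), with 3 higher and 7 lower members. In the immediate early list 4 of 23 were lower and 0 higher (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.0318 by camera, adjusted p = 0.772 with an estimated correlation). The smallest adjusted p were those of Maff (-1.94 ± 0.29, adjusted p = 0.00386) and Egr1. The list mean overlapped between the groups, at -0.91 to -0.20 in GSDMD-NT Alb-cre livers and at -0.75 in control 1, against 0.02 to 0.42 in the other controls. The camera call was lost without control 2 or 4 or GSDMD-NT Alb-cre 5 (adjusted p = 0.0833 to 0.111). Without control 2 or GSDMD-NT Alb-cre 5 the immediate early list had 1 higher member.

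**Figure D5:**
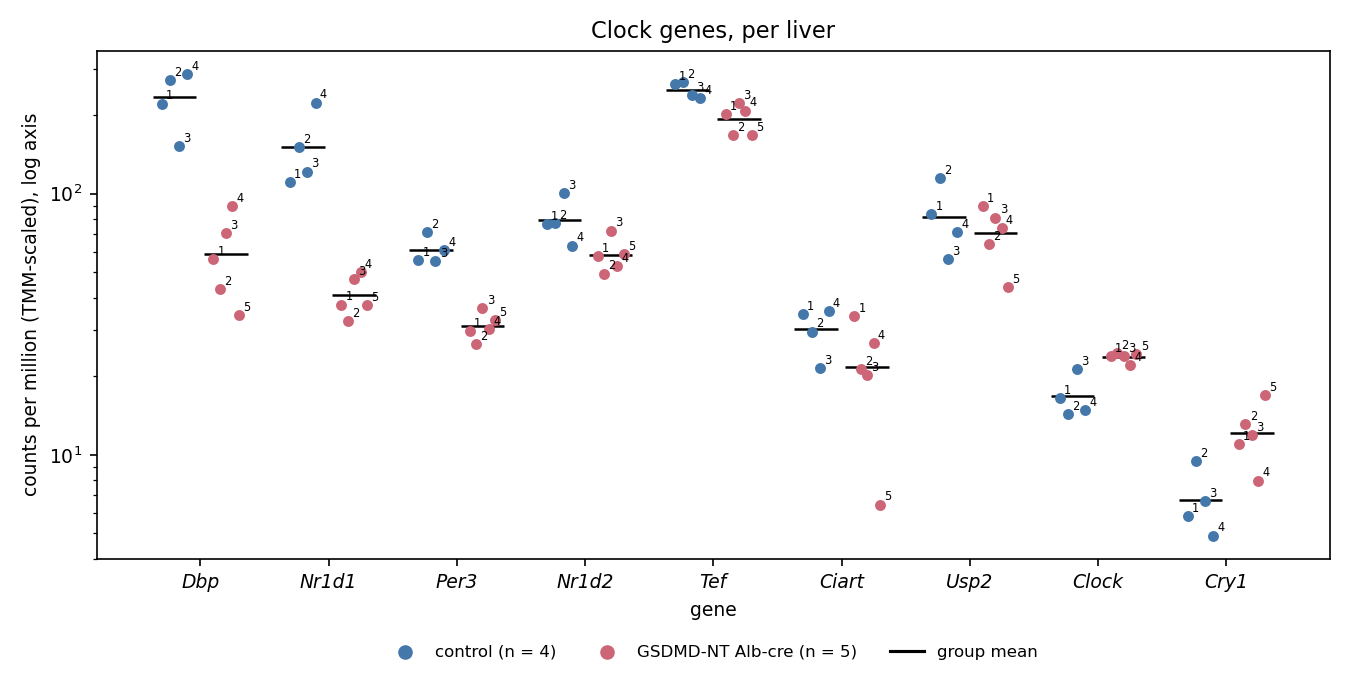
Level of 9 clock genes in each liver (points numbered by replicate, log axis in TMM-scaled CPM), with a bar at each group's mean. Dbp, Nr1d1 and Per3 lie lower in all 5 GSDMD-NT Alb-cre livers than in any control, with the controls for Nr1d1 at 110.6 to 223.4 CPM, and the groups overlap for Ciart and Usp2.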

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

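Of 150 groups of values tested, 9 had 1 liver standing apart from the others by more than the 95% limit of Dixon's ratio (its gap to the nearest liver over the range of the group), and chance gives about 1 in 20. For genes the ratio was taken on log2 CPM, although levels are given below in CPM, and for the total count on plain counts. The tests of neutrophils, transcript length and clock genes below were chosen after the results were seen.

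Control 3 had a total count of 13360000, against 16100000 to 16390000 in the other controls (ratio 0.903). In controls, Gas6 was at 27.8 CPM in control 1 against 40.5 to 42.0 (ratio 0.913), Sc5d at 609 CPM in control 2 against 512 to 525 (ratio 0.856), and Trib3 at 10.6 CPM in control 3 against 18.9 to 19.3 (ratio 0.965). In GSDMD-NT Alb-cre livers, Adh1 was at 1471 CPM in liver 3 against 1109 to 1193 (ratio 0.741), Egr1 at 24.8 CPM in liver 2 against 4.78 to 6.58 (ratio 0.808), H19 at 2.20 CPM in liver 2 against 0.764 to 0.997 (ratio 0.758), and Ntrk2 at 0.382 CPM in liver 1 against 2.13 to 3.72 (ratio 0.736). Mt1 was at 8.65 CPM in GSDMD-NT Alb-cre 3 against 499.7 to 2492 CPM in the other 4 (ratio 0.716), below each control.

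The numbers of called genes were set against other splits of the 9 livers into 4 and 5. Of 100 splits drawn from the 126, the real one included, 1 gave as many higher genes (1296, against 532 at most in another split) and 1 as many lower genes (1270, against 537), which argued against chance for both counts. For the gene lists chance was not excluded, since 77 of the 100 splits called at least as many as the real 14, and up to 29.

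For the acute phase rise a single liver was argued against, since 18 members were called higher without GSDMD-NT Alb-cre 2, the liver with the highest levels. Neutrophils, which carry Lcn2 as well, were argued against as its main source. S100a9, among their most abundant transcripts, averaged 1.18 CPM in GSDMD-NT Alb-cre livers while Lcn2 averaged 746 CPM. More neutrophils in the tissue were not excluded. S100a9 had a log2 fold change of 1.34 ± 0.72 (adjusted p = 0.209), and the neutrophil gene Prtn3 was higher (3.81 ± 1.11, adjusted p = 0.0348, 8.34 ± 11.7 CPM). Of 5 tested neutrophil genes, Lcn2 among them, 2 were higher and 1 was lower. A shift of scaling by abundant genes was argued against, since the 24 members left after their removal had a median log2 fold change of 2.04. Reads shared between paralogs were not tested and stay open for the Saa and Serpina3 genes, families to which Stat3, Steap4 and Hpx do not belong. The Alb-cre genotype and any difference between the livers that the labels do not give stay open, and neither was tested.

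The lower levels of respiratory chain and ribosomal protein genes were weighed against the transcript length trend. For the respiratory chain the median log2 fold change was -0.36 (SD of members 0.26) before and -0.24 (SD 0.22) after correction. The list stayed past camera's threshold at the preset correlation, the outcome set as arguing against the trend as the whole cause. This test cannot decide it, since camera called at least 14 lists in 77 of 100 splits of the livers. A leftover length effect is not excluded. Called members went from 16 to 4 as the shift shrank, and before correction the list was not called with an estimated correlation (adjusted p = 0.767). For ribosomal proteins the trend may account for the fall, since the median went from -0.24 (SD 0.19) to -0.088 (SD 0.18) and camera's call ended as the shift itself shrank. Uneven RNA quality or library preparation stays open, since long intergenic noncoding genes also had 55 lower and 6 higher of 281, and 45 lower and 9 higher after length correction, against 1056 lower and 1249 higher of 12179 protein-coding genes.

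The clock gene changes were set against livers collected at another time of day. Of 7 clock output genes looked at, Dbp, Nr1d1 and Per3 were lower. Nr1d2 (log2 fold change -0.45 ± 0.15, adjusted p = 0.0553), Tef (-0.37 ± 0.12, adjusted p = 0.0551), Ciart (-0.48 ± 0.34, adjusted p = 0.336) and Usp2 (-0.21 ± 0.22, adjusted p = 0.538) did not pass the test. All 7 had a negative log2 fold change, but this says little, since the genes were chosen after some had been seen to fall. Another collection time and a changed clock in livers of this genotype cannot be told apart, since the labels give no collection time.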

How the results depend on the processing

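The length-corrected fit, the fit without controls 2 and 4 and the exact permutation test were chosen after the data were seen. The 1296 higher and 1270 lower genes became 270 and 229 with a replicate block on the description number, and 36 and 58 when tested against a 1.5-fold change, a stricter hypothesis by construction. They became 29 and 44 without controls 2 and 4, and 567 to 1339 and 625 to 1184 with 1 liver left out, lowest without control 2 and control 4, respectively. The title-number replicate block gave 920 and 817 and used 8 livers. Replicate numbers did not pair the livers, since the deviations of same-numbered livers correlated at -0.06 to 0.05, and the fits with blocks use fewer livers. RLE, upper-quartile and total-count scaling, DESeq2, limma-voom, the other filters, removal of abundant genes, 1 surrogate variable and length correction gave 1093 to 1719 higher and 982 to 1597 lower genes. Camera called 14 lists, and 0 were called with an estimated correlation, 7 by fry (6 of the 14 and 1 other), 0 by exact permutation and 13 to 18 with 1 liver left out. After length correction camera called 15. Of 67 called genes given by the naming rule, 50 were called in each fit that left out 1 liver. The call was lost for 55 of these 67 genes without controls 2 and 4. It was lost for 27 with the block on the description number and for 41 against a 1.5-fold change. Directions turned only for genes and lists that were not called. Gsdmd was at -0.027 with 1 surrogate variable and -0.015 to 0.188 with 1 liver left out. Without controls 2 and 4 Col1a1 was at 0.47 and Fasn at 0.21, and Fasn ran from -0.32 to 0.11 with 1 liver left out. The adjusted p of collagens, pointing up under the title-number replicate block, was 0.927, and that of bile acid synthesis, pointing down, 0.996. With 1 liver left out they ran from 0.339 to 0.934 and from 0.404 to 0.934, and that of fatty acid synthesis from 0.388 to 0.963. Where nothing is said of it, the cause was not tested. At 13361093 to 16823506 counts per liver, genes near 1 CPM rest on few counts.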

Other observations

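The lists for the secretory pathway, ribosome biogenesis and glucocorticoid response, and their tests, were chosen after the values of some of their genes were seen, and their adjusted p cover these 4 lists alone.

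Some further lists held calls in both directions. Among 28 genes higher in male than in female mouse liver 4 were higher and 4 lower (4 higher and 4 lower adjusted over the list alone), and 2 to 5 were higher and 2 to 6 lower with 1 liver left out. Among them were the urinary protein gene Mup20, lower (-1.22 ± 0.20, adjusted p = 0.00484), and its relative Mup17, higher (1.88 ± 0.29, adjusted p = 0.00413). The Mup genes are near-identical, so these values are uncertain. Among 15 female-biased genes 3 were higher and 3 lower (4 higher and 5 lower adjusted over the list alone), with Cyp2c40 and Cyp2c69 higher and Ntrk2 lower, at a median of -0.20 although camera pointed up (adjusted p = 0.416). With 1 liver left out 2 to 4 were higher and 2 to 5 lower. Of 36 cell cycle genes 3 were higher, Mcm5 (1.10 ± 0.24, adjusted p = 0.0118) and Mcm4 (1.13 ± 0.30, adjusted p = 0.0263) among them, and 4 were lower, with Ccnb2 (-1.46 ± 0.40, adjusted p = 0.0279) and Cdk1 (-1.11 ± 0.33, adjusted p = 0.038) among those (camera adjusted p = 0.199). With 1 liver left out 1 to 3 were higher and 1 to 3 lower. The scavenger receptor gene Cd163 of resident Kupffer cells was higher (1.67 ± 0.27, adjusted p = 0.00451), as was Timd4 (0.84 ± 0.24, adjusted p = 0.0351), with 2 higher and 0 lower of 16, and 1 or 2 higher and 0 or 1 lower with 1 liver left out. Of 10 erythroid genes 3 were lower and 0 higher, and of 7 T and NK cell genes 0 were called in either direction by edgeR. Albfm1, a gene singled out after its value was seen, fell from 46.5 ± 7.28 CPM to 19 ± 3.14 CPM (-1.29 ± 0.15, adjusted p = 9.51e-04).

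A hypothesis is that the rise of ER folding genes was part of a wider rise of the secretory pathway. In a list of ER-to-Golgi transport genes 21 of 46 tested were higher and 0 lower, at a median log2 fold change of 0.46 or 0.44 after length correction (camera adjusted p = 1.03e-09 after correction), and in an N-glycosylation list 11 of 42 were higher and 1 lower (camera adjusted p = 0.00323). After length correction 8 were higher and 0 lower in the N-glycosylation list (camera adjusted p = 0.000707). Sec23ip (0.93 ± 0.14, adjusted p = 0.00418) and Alg2 (0.99 ± 0.16, adjusted p = 0.00438) had the smallest adjusted p among the higher members named. With an estimated correlation both gave adjusted p = 0.208, and the exact permutation test of list means gave unadjusted p = 0.00794 and 0.0159. Over the 50 lists fixed in advance an exact p of 0.00794 became an adjusted p of 0.132, so these values do not pass what the fixed lists failed, and the genes that prompted the lists are in them.

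A second hypothesis is that Nolc1, Rrp12 and Tsr1 (1.06 ± 0.14, adjusted p = 0.00179, 1.24 ± 0.19, adjusted p = 0.00413 and 1.13 ± 0.21, adjusted p = 0.00642) may mark a wider rise of ribosome biogenesis genes. Of 89 tested 31 were higher and 3 lower (camera adjusted p = 4.61e-08 after length correction, adjusted p = 0.208 with an estimated correlation, exact permutation unadjusted p = 0.00794, which among the 50 fixed lists became an adjusted p of 0.132). Another is that Fkbp5 and Zbtb16 (2.24 ± 0.46, adjusted p = 0.00933) may mark a rise of glucocorticoid-responsive genes. Of 24 tested 7 were higher and 0 lower (camera adjusted p = 0.00569 after length correction, adjusted p = 0.208 with an estimated correlation, exact permutation unadjusted p = 0.0318). Mt1 in that list is also an acute phase gene, and Fkbp5 and Zbtb16, which prompted the list, are in it. Other members were not called, among them Tsc22d3 (0.89 ± 0.40, adjusted p = 0.136), Per1 (0.34 ± 0.46, adjusted p = 0.634), Sgk1 (0.03 ± 0.30, adjusted p = 0.959), Klf9 (-0.205 ± 0.13, adjusted p = 0.298) and Dusp1 (-0.555 ± 0.49, adjusted p = 0.448). As camera at the preset correlation also called lists in other splits of the livers, the camera values of these lists are not proof of either rise.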
